A study of Homo sapiens with 30 samples.

How the data were processed

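HCT116 cells without DICER were transfected with a DICER plasmid and an shRNA or pri-mir-30a plasmid, and small RNA libraries were made from gel-selected RNA with the TruSeq kit, per the labels' protocols. The deposited values are raw counts of reads per read sequence, not normalised, in 1 table for the shRNAs and 1 for pri-mir-30a. The submitters' processing notes name cutadapt, Bowtie2, bedtools and GRCh38, and versions, roles and filters are not given in the sources used here. There were 2757 shRNA sequences and 1447 pri-mir-30a sequences. Each row gives a read's sequence and its template start and end, and a read may carry up to 2 further bases at its 3′ end. Reads were 18 to 41 and 18 to 54 bases long. The kit has no molecular identifiers named in the labels, so reads are not independent molecules.

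Column names give the DICER form, a number that is not explained and the replicate. Each column was filled under 1 precursor only, and that precursor, as the authors name it in the table, was taken as the construct. The precursor named with the letters au was matched to MT because the other was named wt. Of the sequences, 757 in the shRNA table and 227 in the pri-mir-30a table were listed under more than 1 precursor, yet each column counted them under 1, so reads of another construct in a library would not have been seen as such. The construct behind every value rests on this reading.

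The most common base at each position gave each precursor's sequence. Reads not matching it made up 0.0387% of the shRNA reads and 0.137% of the pri-mir-30a reads. RNAfold 2.7.2 folded the precursors, for the shRNAs the first 55 bases. Reads were sorted into 5p arm, 3p arm, arm with loop, flanks and other. Shares with their 95% Wilson intervals were computed per library. A share of 0 allows 3 counts of the library, which was 0.0303% in the shallowest pri-mir-30a library and 0.0223% in the shallowest shRNA library.

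The tests had been fixed for tables of microRNAs before the data were examined. The tables held only reads of the transfected hairpins, so those tests were run on product classes and on the hairpin's own arms. Tests of endogenous microRNAs, of gene lists and of arm ratios over many hairpins were not run. Product classes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit on group means, Benjamini-Hochberg threshold 0.05), which kept 207 shRNA classes and 186 pri-mir-30a classes holding 99.9% of reads in each table. TMM factors ran from 0.124 to 2.80 and from 0.165 to 4.03, which is far from 1, so counts of higher and lower classes are also given with library-size scaling. A comparison of DICER forms averages the effect over constructs. Shares of reads by first or last base, and by read class, were tested in the same way with the reads of that arm as library size and no further scaling, for positions with a mean of at least 10 counts. Adjustment ran over 9 first and 11 last positions of shRNA 3p reads, 10 last positions of 5p and 8 first positions of 3p pri-mir-30a reads, and 6 pri-mir-30a read classes. These position tests were chosen after seeing the data. DESeq2 1.42.0 served as an alternative. Single values per library were compared by exact two-sided permutation, within shRNAs or over 4 against 4 pri-mir-30a libraries, and the log2 arm ratio used a pseudocount of 0.5.

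Product classes named in the text follow a rule set beforehand for rows without microRNA names: up to 8 rises and 8 falls per comparison with DICER-WT, past the threshold, with a mean log2 CPM of at least 6 and 1 direction in every construct, and 3 each way between constructs. CPM here was computed from the deposited counts. Positions were named after their values were seen.

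The product test was tested on simulated data with the real depths and dispersions, in 30 draws. Every group had the same profile, the mean over all libraries, and rises and falls were equal in number. The rates therefore do not cover the real differences between constructs or the scaling they bring. For D1709A against DICER-WT over 207 classes it recovered 57.9% of 2-fold, 94% of 4-fold and 99% of 16-fold changes, and called 5.4% of unchanged classes. For E1564A against DICER-WT over 186 classes it recovered 4.41%, 18.2% and 73.6%, and called 0.816% of unchanged classes. The pri-mir-30a counts had a common dispersion of 0.631, against 0.11 for the shRNAs, so smaller changes there were mostly missed. The position test with no effect gave at least 1 call in 9% of 500 draws for D1709A and 6.2% for E1564A, so its adjusted p-values near 0.05 are somewhat too small. No replicates agreed within counting noise (chi-square per degree of freedom 3.94 to 314), so none were treated as 1 library given more than once. This does not show that they came from separate cultures. Normalisation, low-count filter, tool, replicate block, the samples fitted and single libraries left out were varied.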

Results

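Small RNA libraries were made from HCT116 cells, a human colorectal carcinoma line, in which DICER had been knocked out. DICER is the RNase III enzyme that cuts precursor hairpins into small RNAs of about the length of a microRNA. Its RNase IIIb domain, which holds D1709, cuts the 5p strand of a hairpin, and its RNase IIIa domain, which holds E1564, cuts the 3p strand. The cells received a plasmid for a DICER form together with a plasmid for a hairpin, and RNA was taken 48 h later. The series had 30 libraries in 15 groups of 2. In 18 libraries DICER-WT, D1709A or D1709N met 1 of 3 short hairpin RNAs (shRNAs), sh21bp, sh22bp or sh2122bp. In the other 12 libraries DICER-WT, E1564A or E1564Q met 1 of 2 forms of pri-mir-30a, named WT and MT in the labels. The question that the series title gives is which features determine where DICER cuts.

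The measurement was the count of each read sequence of the transfected hairpin. The shRNA libraries held 13426 to 1249529 such reads and the pri-mir-30a libraries 9898 to 911570. The shallowest of each kind were D1709N with sh22bp, replicate 1, and DICER-WT with pri-mir-30a MT, replicate 1. Positions count from 1 at the first base of each hairpin. Values are means over libraries with the SD and the number of libraries, and every group had n = 2. The labels do not say that replicates were separate cultures, so p-values cover no spread beyond that between these libraries. The edgeR fits also pool this spread over groups and borrow it across product classes or positions. Very small edgeR p-values rest on that pooling, and not on the 2 libraries of a group alone.

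Over the bases compared, the 3 shRNAs differed at positions 21 and 22 only. The sequence built from the reads was 63 bases long for sh22bp, with a further T at its end, and 62 for the others. Since this length rests on how far reads reached, it does not show that the constructs differ there. From sh21bp to sh22bp the substitutions were A21T and T22A, and from sh21bp to sh2122bp the substitution was T22A. In the predicted folds, base 21 was paired with base 34 in sh21bp and unpaired in sh22bp, and base 22 was unpaired in sh21bp and paired with base 33 in sh22bp. Both bases were paired in sh2122bp. The predicted energies were -26.20, -26.70 and -30.00 kcal/mol for sh21bp, sh22bp and sh2122bp. Nearly every read came from the 3p arm, which averaged 99.8% ± 0.104 of reads (SD, n = 6) with DICER-WT, 99.6% ± 0.196 with D1709A and 99.9% ± 0.0424 with D1709N. The 3p reads therefore show where the 3p strand was cut, and the 5p cut was read from too few reads to place.

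With DICER-WT, the first base of the 3p reads depended on the shRNA. With sh21bp, 93.5% ± 0.272 (SD, n = 2) of 3p reads started at base 36 and 3.51% ± 0.0507 at base 35. With sh22bp, 56.5% ± 5.29 started at base 35, 20.7% ± 0.102 at base 34, 11.8% ± 4.95 at base 37 and 10.7% ± 0.153 at base 36. With sh2122bp, 58.5% ± 0.611 started at base 35, 26.2% ± 0.35 at base 36 and 13.7% ± 0.115 at base 34. Relative to sh21bp, the share at base 35 rose in sh22bp by 4.01 (SE 0.08) and in sh2122bp by 4.06 (SE 0.08) on the log2 scale, with adjusted p of 5.49e-15 and 4.83e-15 in edgeR's quasi-likelihood test. The share at base 36 fell by 3.12 (SE 0.07) and 1.84 (SE 0.06) on that scale. Between sh22bp and sh2122bp the share at base 36 was higher in sh2122bp by 1.29 (SE 0.06) and that at base 37 was lower (log2 fold change -3.33, SE 0.44), while base 35 did not pass (adjusted p = 0.48).

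**Figure D1:**
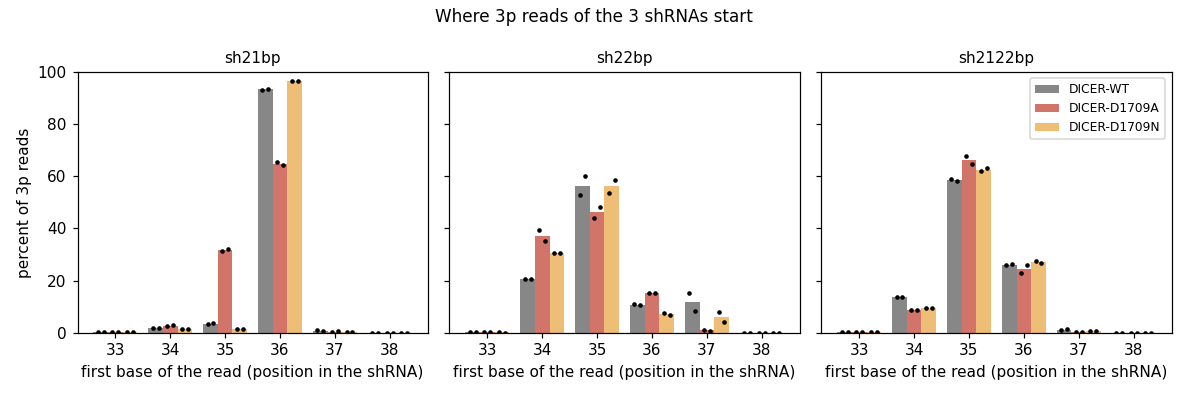
Percent of 3p reads (vertical axis) by the first base of the read in the shRNA (horizontal axis), for 3 DICER forms and 3 shRNAs. Bars are means, points are the 2 libraries. With sh21bp the share at base 35 was 3.51% with DICER-WT, 31.7% with D1709A and 1.48% with D1709N.

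Across DICER forms the shRNAs also differed in whole products. A product class here is a first base, a last template base and any further bases at the 3′ end. Of 207 classes tested, 127 differed between sh22bp and sh21bp (67 higher and 60 lower in sh22bp), 111 between sh2122bp and sh21bp (49 higher, 62 lower) and 85 between sh2122bp and sh22bp (47 higher, 38 lower). Scaling by library size alone gave 108 higher and 38 lower for the first pair, 90 higher and 26 lower for the second and 47 higher and 37 lower for the third, so the split by direction rested on the scaling for the first 2. For these the median class moved from 0.06 to 1.58 and from -0.57 to 1.01 on the log2 scale between the scalings. The class from base 36 to base 59 was lower in sh22bp than in sh21bp (log2 fold change -7.78, SE 0.67) and in sh2122bp than in sh21bp (-5.44, SE 0.60). The class from base 37 to base 59 was lower in sh2122bp than in sh22bp (-4.40, SE 0.71). Without D1709A replicate 1 of sh21bp the first pair of calls was lost (-5.89 and -3.67), and without D1709A replicate 1 of sh22bp the last (-2.41).

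With D1709A, more sh21bp 3p reads started 1 base earlier. Of these reads 31.7% ± 0.451 (SD, n = 2) started at base 35 and 64.9% ± 0.92 at base 36, against 3.51% and 93.5% with DICER-WT. The change at base 35 was 3.18 (SE 0.08, adjusted p = 6.27e-14, edgeR) and that at base 36 was -0.53 (SE 0.06) on the log2 scale. With sh22bp the share at base 34 rose from 20.7% to 37.2% ± 2.83 (0.85, SE 0.08) and the share at base 35 fell from 56.5% to 46.2% ± 2.97 (-0.29, SE 0.07). With sh2122bp the share at base 34 instead fell, from 13.7% to 8.65% ± 0.177 (-0.67, SE 0.08), and base 35 rose to 66.3% ± 2.11 (0.18, SE 0.07). That rise vanished (-0.00067) with TMM factors over positions, which replace shares by ratios to other positions. The share at base 37 was lower in every shRNA, and over the 3 shRNAs by -2.36 (SE 0.25, adjusted p = 1.92e-06).

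The 3′ ends changed as well with D1709A. Over the 3 shRNAs, 3p reads ending at base 56 rose (log2 fold change 0.61, SE 0.08) and those ending at base 57 and base 58 fell (-1.86, SE 0.28, and -3.24, SE 0.25). With sh2122bp, reads ending at base 56 were 21.9% ± 0.519 with DICER-WT and 30.7% ± 1.09 with D1709A. Of 207 product classes 97 differed, 36 higher and 61 lower, against 29 higher and 62 lower with library-size scaling. Among the falls were the classes from base 37 to 58 (-3.40, SE 0.29, adjusted p = 2.06e-10 in edgeR), base 34 to 54 with an added C (-3.53, SE 0.32) and base 37 to 57 with an added C (-3.23, SE 0.36). The class from base 36 to 59 (-7.08, SE 0.72) had 2256 reads over the DICER-WT libraries and 7 over the D1709A libraries. That from base 37 to 59 (-5.95, SE 0.70) had 1698 and 8. Reads per shRNA were 583593 to 1595063 with DICER-WT and 162905 to 224345 with D1709A, so the raw counts overstate these falls. Among the rises were base 35 to 56 (1.70, SE 0.32), base 35 to 55 with added UA (1.39, SE 0.24), base 32 to 56 (1.71, SE 0.35) and base 31 to 56 (1.65, SE 0.36). These 4 rises missed the threshold without a low-count filter, at 0.99, 0.68, 1.00 and 0.96.

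With D1709N, base 36 stayed the main start of sh21bp 3p reads. It took 96.7% ± 0.045 (SD, n = 2) of its 3p reads, against 93.5% with DICER-WT, and did not pass the test (adjusted p = 0.501, edgeR). From 93.5% a share has too little room to rise for this log2 test to pass, so it cannot tell whether base 36 rose. The D1709N libraries, at 96.69% and 96.75%, lay above the DICER-WT libraries, at 93.30% and 93.68%. Base 35 fell from 3.51% to 1.48% ± 0.0941 (log2 fold change -1.25, SE 0.07). With sh22bp the share at base 34 rose to 30.6% ± 0.0566 (0.56, SE 0.08) and that at base 36 fell to 7.02% ± 0.58 (-0.61, SE 0.06). With sh2122bp the share at base 34 fell to 9.36% ± 0.0493 (-0.55, SE 0.08). Over the 3 shRNAs the share at base 37 fell by 1.51 (SE 0.24) on the log2 scale. Of 207 product classes 26 differed, 18 higher and 8 lower. Scaling by library size alone gave 101, none higher, with the median class at -0.98 instead of 0.04 on the log2 scale. The class from base 37 to 58 was lower (-0.81, SE 0.26; adjusted p = 0.0649 without a low-count filter, edgeR). That from base 34 to 56 was 1.11 (SE 0.29) higher with TMM scaling and 0.12 (adjusted p = 0.477) with library size, and it missed the threshold without any 1 of the 18 libraries, so its rise does not hold. The count and its split by direction also moved with the filter (5 with none, 0 higher and 5 lower) and the tool (12 in DESeq2, 5 higher and 7 lower). With only DICER-WT and D1709N fitted the count was 47, 3 higher and 44 lower. It was 13 without DICER-WT sh21bp replicate 1, 15 without DICER-WT sh2122bp replicate 1, 46 and 48 without D1709A sh22bp replicate 1 and 2, and 43 without D1709A sh2122bp replicate 1.

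Set against each other, D1709A had more sh21bp 3p reads at base 35 than D1709N (log2 fold change 4.43, SE 0.08, adjusted p = 2.05e-15, edgeR) and fewer at base 36 (-0.58, SE 0.06). With sh22bp, base 36 was higher in D1709A (1.12, SE 0.06) and base 37 lower (-2.75, SE 0.43). With sh2122bp, bases 34 and 35 did not pass (adjusted p = 0.201 and 0.256). Of 207 product classes 98 differed, 37 higher and 61 lower in D1709A, against 69 higher and 34 lower with library-size scaling and 54 in all without a low-count filter. Fold changes of the substitutions against DICER-WT were nearly uncorrelated across product classes (r = 0.0064, where unchanged groups set against the same DICER-WT libraries gave 0.280 on average), and product classes are not independent replicates.

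The share of 5p reads among arm reads was tiny for every shRNA library. It averaged 0.0124% ± 0.00829 (SD, n = 6) with DICER-WT, 0.0185% ± 0.0150 with D1709A and 0.00395% ± 0.00547 with D1709N. The exact two-sided permutation p within shRNAs was 0.38 for D1709A and 0.0463 for D1709N, which became 0.483 and 0.162 after Benjamini-Hochberg adjustment over 14 comparisons. The log2 ratio of 5p to 3p reads gave an exact permutation p of 0.509 and 0.037, adjusted to 0.594 and 0.162. The smallest p that these permutations can give is 0.0093. Averaged over shRNAs, the share at the main start of each shRNA under DICER-WT differed by -10.4 percentage points in D1709A (exact permutation p = 0.139), a mean over falls in sh21bp and sh22bp and a rise in sh2122bp, and by 2.35 in D1709N (exact permutation p = 0.157), each with an adjusted p of 0.367. For D1709N, counting within 1 base of the main start gave 2.39 (exact permutation p = 0.0093, the smallest possible). Leaving out DICER-WT sh22bp replicate 1 gave 1.10, replicate 2 gave 3.59 (exact permutation p = 0.0185), and leaving out D1709N sh22bp replicate 2 gave 1.52.

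The human MIR30A gene lies on chromosome 6 from 71403551 to 71403621 on the minus strand (GRCh38, GENCODE 29), inside the lincRNA genes LINC00472 and AL136164.2. Its 71-base transcript matches the WT precursor from base 19. The 5p product ending at base 46 maps to 71403594 to 71403616, and the one ending at base 47 maps to 71403593 to 71403616. The 3p product from base 65 maps to 71403554 to 71403575. The MT precursor differs from WT by C46A, A58C and G64T, and bases 46 and 64 were predicted to pair with each other in both. The predicted energies were -47.60 kcal/mol for WT and -45.90 for MT.

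With DICER-WT, 5p reads ended 1 base earlier more often in the MT precursor. In WT, 65.6% ± 4.99 (SD, n = 2) of 5p reads ended at base 47 and 26% ± 3.24 at base 46. In MT, 32.7% ± 2.92 ended at base 47 and 48% ± 7.43 at base 46. The fall at base 47 had an adjusted p of 5.98e-04 in edgeR, and the rise at base 46 was 0.88 (SE 0.19) on the log2 scale. That rise turned to -0.13 with TMM factors over positions, which replace shares by ratios to other positions and so do not test the share itself. Reads of the 3p arm started at base 65 in 82.6% ± 5.36 of cases in WT and 46.8% ± 29.6 in MT, which did not pass (adjusted p = 0.232, edgeR). Starts at base 66 rose in MT, from 16.8% ± 5.78 to 52.1% ± 30.3 (1.63, SE 0.53, adjusted p = 0.0137), and so did starts at base 64, 1 of the 3 differing bases, from 0.0697% to 0.787% (3.42, SE 0.69). Base 47 is T in both precursors, so a product ending at base 46 with 1 added U cannot be told from one ending at base 47. Over the 3 DICER forms 62 of 186 product classes differed, 19 higher and 43 lower in MT, against 45 higher and 36 lower with library-size scaling, where the median class was at 0.52 instead of -0.48. Of the 62, 14 had reads from 1 precursor only and 16 ended at base 45 with added bases, where the differing base 46 sets which added bases can be seen. The class from base 24 to 45 with an added A, 59454 reads in WT, has the sequence of the MT product from base 24 to 46. With an added C, 10269 reads in MT, it has the sequence of that product in WT. Additions and reads of the other precursor cannot be told apart there.

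**Figure D2:**
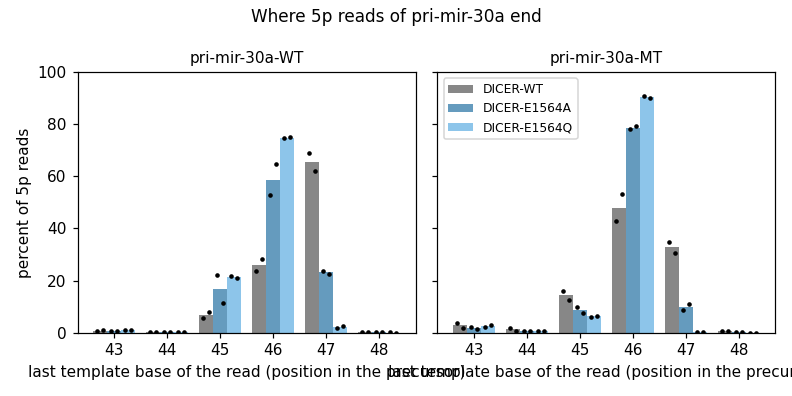
Percent of 5p reads (vertical axis) by the last template base of the read (horizontal axis), for 3 DICER forms and both pri-mir-30a precursors. Bars are means, points are the 2 libraries. In the WT precursor base 47 took 65.6% with DICER-WT, 23.2% with E1564A and 2.3% with E1564Q.

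Both substitutions of E1564 lowered the 3p-arm share of pri-mir-30a reads. With the WT precursor it was 3.93% ± 2.11 (SD, n = 2) with DICER-WT, 0.306% ± 0.0673 with E1564A and 0.269% ± 0.0319 with E1564Q. With MT it was 16.5% ± 15.1, 0.599% ± 0.0107 and 0.719% ± 0.296. The DICER-WT replicates with MT were far apart, at 27.1% in replicate 1 (95% Wilson interval 26.2 to 28.0%) and 5.82% (5.63 to 6.01%) in replicate 2. Intervals cover counting error only. Over both precursors the change was -4.23 (SE 0.54, adjusted p = 1.9e-08, edgeR) for E1564A and -4.19 (SE 0.54, adjusted p = 2.27e-08) for E1564Q. The 5p share of arm reads was 89.7% ± 11.5 (SD, n = 4) with DICER-WT, 99.5% ± 0.18 with E1564A and 99.5% ± 0.312 with E1564Q, with all libraries of each substitution above all DICER-WT libraries. The exact two-sided permutation p was 0.0286 for each, the smallest that 4 libraries against 4 can give, and 0.049 after adjustment over 12 comparisons. The log2 ratio of 5p to 3p reads rose by 4.13 in both, with the same exact permutation p. This ratio restates the 5p share of the same reads. Such ties at the smallest p bring the adjusted value under 0.05, so it is no firm pass. Exact permutation within precursors gave p = 0.0556 for these 4 comparisons, the smallest that scheme can give.

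**Figure D3:**
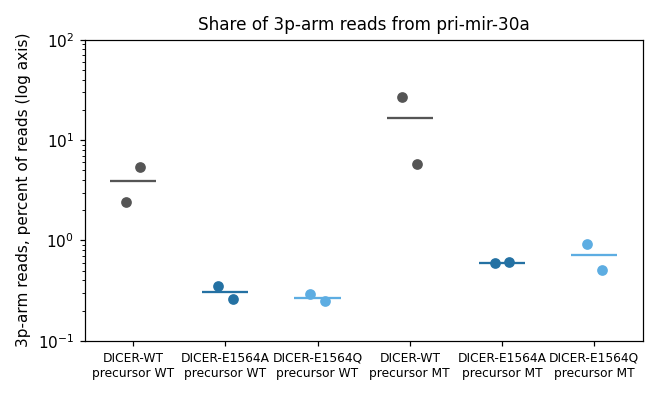
Share of 3p-arm reads among pri-mir-30a reads (log axis, percent) per library, with the mean of each group as a line. The DICER-WT libraries lie between 2.44% and 27.1%, and the E1564A and E1564Q libraries lie between 0.247% and 0.928%.

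Fewer 5p reads ended at base 47 and more at base 46 with both substitutions. With the WT precursor, base 47 fell from 65.6% to 23.2% ± 0.852 (SD, n = 2) with E1564A and 2.3% ± 0.463 with E1564Q, and base 46 rose from 26% to 58.8% ± 8.64 and 74.9% ± 0.286. With MT, base 47 fell from 32.7% to 9.87% ± 1.83 and 0.136% ± 0.032, and base 46 rose from 48% to 78.8% ± 0.619 and 90.5% ± 0.694. Over both precursors base 47 changed by -1.62 (SE 0.17, adjusted p = 3.76e-12, edgeR) with E1564A and by -6.37 (SE 0.22, adjusted p = 1.78e-36) with E1564Q. Base 46 rose by 0.95 (SE 0.13) and 1.22 (SE 0.13). The main end under DICER-WT was base 47 in WT and base 46 in MT. Its share differed by -5.82 points with E1564A (exact permutation p = 0.714) and -10.4 with E1564Q (exact permutation p = 0.6), and neither passed. Since this mean offsets the fall at base 47 in WT with the rise at base 46 in MT, it cannot tell whether ends moved. By exact permutation over the libraries, base 47 gave p = 0.0286 for each substitution (adjusted 0.049). Base 46 gave an exact permutation p of 0.0571 for E1564A and 0.0286 for E1564Q (adjusted 0.0857 and 0.049). These permutations ignored the precursor, and exact permutation within precursors cannot give a p under 0.0556. The adjusted 0.049 again rests on ties at the smallest p. Of WT-precursor reads ending at base 46 with no added base or 1 A, C or G, those with the added base were 42.3% with DICER-WT, 8.89% with E1564A and 0.529% with E1564Q. In MT they were 7.26%, 1.36% and 0.0306%. Over both precursors added A and added C fell with E1564A by edgeR (log2 fold change -2.72, SE 0.26, and -2.41, SE 0.24, adjusted p = 8.23e-06 for each). The exact permutation p of the pooled share, which ignores the precursor, was 0.143 for E1564A and 0.0286 for E1564Q.

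The few 3p reads left with the substitutions started at base 65 less often. Over both precursors the share starting at base 65 changed by -3.67 (SE 0.41) with E1564A and -4.29 (SE 0.42) with E1564Q, and the share at base 64 rose by 6.33 (SE 0.49) and 4.87 (SE 0.47). Rises at bases 61, 62 and 63 were 7.81 (SE 0.85), 7.25 (SE 0.72) and 6.77 (SE 0.69) with E1564A and 5.34 (SE 0.81), 5.77 (SE 0.70) and 5.85 (SE 0.67) with E1564Q. Starts also moved later, with rises at base 67 of 7.84 (SE 0.76) and 5.40 (SE 0.72). In WT, base 66 took 16.8% ± 5.78 (SD, n = 2) of 3p reads with DICER-WT and 65.2% ± 2.27 with E1564Q (log2 fold change 1.95, SE 0.53, adjusted p = 7.44e-04 in edgeR). In MT it took 52.1% ± 30.3 and 80.7% ± 2.53, which did not pass (0.63, SE 0.52, adjusted p = 0.227). Over both precursors the E1564Q change was 1.29 (SE 0.37). It turned to -1.22 with TMM factors over positions, which replace shares by ratios to other positions. With E1564A, base 66 fell in MT (-1.67, SE 0.53, adjusted p = 0.0035, edgeR) and did not pass over both (-0.57, SE 0.37). With E1564A and MT, base 64 took 41.4% ± 1.79. These shares rest on 1545 3p reads for E1564A with WT and 2524 with MT, over both replicates. With DICER-WT, starts at base 61 were 10 of 12567 3p reads in WT and 1 of 6132 in MT. They were 12 and 2 at base 62, 23 and 3 at base 63, 9 and 52 at base 64, and 4 and 5 at base 67. The sizes of the fitted rises at these bases are therefore uncertain.

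Of 186 product classes, 101 differed between E1564A and DICER-WT (39 higher, 62 lower) and 123 between E1564Q and DICER-WT (53 higher, 70 lower). With library-size scaling the first split was 31 higher and 79 lower and the second 18 higher and 94 lower, the second with the median class at -2.43 instead of -0.32. A filter at a mean of 20 counts left 52 and 59 calls. It takes low-count classes out of the test, so these calls are not out of 186. Falls in both included the classes from base 65 to 87, with 629 reads over the DICER-WT libraries, 4 with E1564A and 3 with E1564Q, and from base 26 to 47 with an added U, with 538, 3 and 8. Rises in both included base 67 to 86, with 2 reads in DICER-WT, 468 in E1564A and 273 in E1564Q, and base 63 to 86 (log2 fold change 5.97, SE 1.54, and 7.23, SE 1.52), with 9, 228 and 388. Reads in all were 391484 in WT and 69174 in MT with DICER-WT, and 530469 and 422407 with E1564A. With E1564Q they were 1474157 and 1168836, so these raw counts are not comparable between DICER forms. TMM factors were 1.13 to 4.03 with DICER-WT and 0.165 to 2.36 with E1564Q, so the fitted folds rest in part on the scaling. Fitted folds of such classes are no bounds. The 2 sets of fold changes correlated across classes (r = 0.904). Unchanged groups set against the same DICER-WT libraries gave 0.682 on average, and separate sets of DICER-WT libraries gave 0.833 to 0.863. The covariance was 15.7 against 1.06 in the simulation. Both were higher in 37 classes and lower in 55, where independent lists would share 11.1 and 23.3. Because both were set against the same DICER-WT libraries, the lists are not independent, and the overlap of unchanged groups was not recorded.

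E1564A kept more 5p reads at base 47 than E1564Q (log2 fold change 4.76, SE 0.20, adjusted p = 2.8e-31, edgeR), and base 46 did not pass (-0.27, SE 0.13, adjusted p = 0.08). The 3p-arm share did not pass either (-0.04, SE 0.48). Of 186 product classes 21 differed, 6 higher and 15 lower in E1564A, while library-size scaling gave 48, with 46 higher and the median class at 1.06. The count was 33 with a filter at a mean of 20 counts (27 higher, 6 lower) and 35 in DESeq2 (16 higher, 19 lower). It was 32 without DICER-WT MT replicate 1, 8 without E1564A WT replicate 2, 6 without either E1564A MT replicate, 5 without E1564Q WT replicate 1 and 40 without E1564Q MT replicate 2.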

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

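The tests of explanations and the counts of regroupings in this part had their predictions written after the results were seen, and the position tests were chosen after seeing the data. Groups of 2 libraries are too small for a test of single libraries that stand apart.

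The effect of D1709A on product classes differed among the 3 shRNAs in 45 of 207 classes, and that of D1709N in 9, by edgeR interaction tests. The count for D1709A was 68 to 81 without DICER-WT sh2122bp replicate 1, either D1709A sh22bp replicate, D1709A sh2122bp replicate 2, D1709N sh22bp replicate 1 or D1709N sh2122bp replicate 1. That for D1709N was 17 and 14 without D1709A sh22bp replicate 1 and 2 and 4 or fewer without most other libraries, so single libraries decide it. Without a low-count filter the counts were 15 and 0, and for D1709N the count was 4 with library-size scaling, 3 with the replicate block and 2 in DESeq2. For the first base of 3p reads the adjusted interaction p of D1709A was 4.42e-08 at base 34, 1.39e-12 at base 35, 4.85e-07 at base 36 and 0.0044 at base 37. For D1709N it was 1.74e-06, 7.65e-08, 1.46e-05 and 0.0212 at the same bases. The effect of E1564Q differed between precursors in 1 of 186 classes, 27 without E1564Q MT replicate 1, 4 without DICER-WT MT replicate 2 and 0 without 8 other single libraries. For the last base of 5p reads the adjusted interaction p was 5.02e-05 at base 45 for E1564A, and 1.21e-08 at base 45 and 2.2e-11 at base 47 for E1564Q. For the first base of 3p reads it was 0.0383 at base 66 for E1564A and 0.0049 at base 64 for E1564Q.

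Reads of the 5′ flank of pri-mir-30a, which enter no comparison of arms, averaged 1.69% ± 0.774 (SD, n = 4) with E1564A, 0.41% ± 0.271 with E1564Q and 0.275% ± 0.274 with DICER-WT. Every E1564A library, at 1.04% or more, lay above every DICER-WT library, at 0.677% or less. The change over both precursors was 2.84 (SE 0.90, adjusted p = 0.0062, edgeR) on the log2 scale. It did not pass in MT alone (2.41, SE 1.25, adjusted p = 0.128) or against E1564Q (1.95, SE 0.86, adjusted p = 0.0889). Over both precursors the 3′ flank rose with E1564A as well (2.87, SE 0.90, adjusted p = 0.0062), but did not pass in MT alone (1.60, SE 1.27, adjusted p = 0.26). The DICER-WT libraries held 9 such reads in WT and 8 in MT, and 1 of those libraries, at 0.0505%, lay above both E1564A libraries with the WT precursor.

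The rise of sh21bp reads starting at base 35 with D1709A was weighed against reads from other D1709A libraries. A mix with sh22bp reads large enough to give the rise would bring at least 24.6% of reads starting at base 34, and a mix with sh2122bp reads at least 3.89%. The share seen was 2.69% ± 0.191 (SD, n = 2), which argues against both. The difference in DICER form, which the design names, stays open and was not tested apart from the comparison itself.

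The move of 5p ends from base 47 to base 46 with E1564A and E1564Q may come in part from fewer added U bases, since a U after base 46 reads as template base 47. If so, added A, C or G after base 46 should fall too. Pooled, their share changed by -2.25 on the log2 scale with E1564A and -6.32 with E1564Q, in the precursor with the smaller fall (exact permutation p = 0.143 and 0.0286 over both). By edgeR over both precursors with E1564A, added A (-2.72, SE 0.26), C (-2.41, SE 0.24) and G (-2.00, SE 0.72, adjusted p = 0.0227) each fell, though G did not pass in the WT precursor alone (0.14, SE 0.97, adjusted p = 0.892). Added U after base 47 was 8.02% of reads ending there with DICER-WT, 1.65% with E1564A and 1.56% with E1564Q in the WT precursor, and 27.6%, 5.76% and 11.2% in MT. At base 45 in the WT precursor with E1564Q, additions of 2 bases fell from 11.1% to 0.0505% (-7.77, SE 0.70), whereas 1 added U rose from 49.4% to 84.4% (0.77, SE 0.18, adjusted p = 0.0057, edgeR). Added U at base 45 also rose with E1564A in WT (0.66, SE 0.18, adjusted p = 0.013, edgeR). In MT it rose with E1564A (1.22, SE 0.19) and with E1564Q (1.31, SE 0.19). Added U was thus lower at base 47 and higher at base 45 with both substitutions in both precursors, so not every addition fell. A changed cut and a changed addition of bases both stay open.

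In regroupings of the libraries, each fit kept the other factor (construct, or DICER form for comparisons of constructs). Only a split that matched this factor was fitted without it. For E1564A (98 classes) and E1564Q (107), only the real split, 1 of 35, gave as many classes. The highest other split, with 9 and 7, was that by precursor, and the highest of the rest gave 0 and 1. Between E1564A and E1564Q, 2 of 35 splits gave as many as the real 25, and the other was the split by precursor, with 38. Chance is not excluded there by that count, and the highest of the remaining splits gave 5. For each remaining comparison, only the real split gave as many classes among 100 drawn of 462 splits. The real count and the highest other were 81 and 35 for D1709A, 16 and 10 for D1709N, and 57 and 38 for D1709A against D1709N. They were 115 and 57 for sh22bp against sh21bp, 108 and 65 for sh2122bp against sh21bp, and 80 and 38 for sh2122bp against sh22bp. For pri-mir-30a MT against WT they were 61 and 1. Other splits mix the groups compared, which widens the spread and favours the real split. Counts of 1 of 35 or 1 of 100, the lowest possible, therefore do not exclude chance or another difference between the libraries.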

How the results depend on the processing

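TMM factors and DESeq2 at the level of positions were chosen after seeing the data; the other alternatives were planned. Of 99 position results, DESeq2 kept direction and side of the threshold in 95 and ended the call in 4. TMM factors kept 63, ended 17, made 7 pass and turned 12, and since a trimmed mean over so few positions replaces shares by ratios to other positions, this follows from its construction. The turned log2 values were -2.03 (D1709A, sh21bp, base 34), -0.00067 (D1709A, sh2122bp, base 35), 0.71 (D1709N, sh21bp, base 34), 0.50 (D1709N, sh22bp, base 35), -1.22 (E1564Q, 3p base 66), -2.75 and -1.85 (D1709A against D1709N, sh21bp, bases 34 and 37), -0.21 (the same, sh22bp, base 34), -0.29 (sh22bp against sh21bp, base 34), -0.56 and -2.91 (sh2122bp against sh21bp, bases 34 and 37) and -0.13 (pri-mir-30a MT against WT, 5p base 46). Leaving out single libraries kept 1586 position values, ended the call in 74 and made 8 pass.

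Same-numbered libraries did not deviate together throughout. The correlation ran from -0.243 to 0.482 for pri-mir-30a (median 0.149, over 0.1 in 9 of 15 pairs of groups) and from -0.381 to 0.34 for the shRNAs (median 0.0162, 12 of 36), so they were taken to share only a number. The replicate block gave 99 classes for E1564A, 118 for E1564Q, 16 for E1564A against E1564Q, 63 for MT against WT, 99 for D1709A, 23 for D1709N and 97 for D1709A against D1709N, kept all 99 position results, and gave 3 for the D1709N interaction. Sign flips of same-numbered pairs cannot pass for pri-mir-30a (smallest p 0.125): differences in 5p share of 9.80 and 9.76 points and log2 arm ratios of 4.13 for both no longer passed, as within precursors.

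A filter changes which classes are tested, so counts under other filters have other totals. Counts of classes changed by more than 1.5 times as follows, and the cause was not tested. Library size alone gave 48 for E1564A against E1564Q, 101 for D1709N, and 4 each for the E1564Q and D1709N interactions. No low-count filter gave 5 for D1709N, 54 for D1709A against D1709N, 15 and 0 for the D1709A and D1709N interactions, and 6 and 2 for the E1564A and E1564Q interactions. A mean of at least 20 counts gave 52 for E1564A, 59 for E1564Q, 33 for E1564A against E1564Q, and 3 and 17 for their interactions. DESeq2 gave 35 for E1564A against E1564Q, 12 for D1709N, 3 for the E1564Q interaction and 2 for the D1709N interaction. DESeq2 size factors gave 2 for the E1564Q interaction. Fitting only DICER-WT and D1709N gave 47. The E1564A interaction had 0 classes in edgeR and 12 at an unadjusted p under 0.05. A pseudocount of 5 gave an arm ratio of -1.43 for D1709N, with an unadjusted exact permutation p of 0.111 instead of 0.037. Counting within 1 base of the main end gave 2.39 points for D1709N, with an unadjusted exact permutation p of 0.0093 instead of 0.157. In the main analysis neither passed after adjustment.

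Leaving out 1 library in turn gave ranges of 31 to 81 (D1709A interaction), 0 to 17 (D1709N interaction), 13 (without DICER-WT sh21bp replicate 1) to 48 (without D1709A sh22bp replicate 2) for D1709N, 0 to 3 and 0 to 27 (E1564A and E1564Q interactions) and 5 to 40 (E1564A against E1564Q). Ranges were 4.42 to 15.2 and 4.39 to 15.1 points for the 5p share of E1564A and E1564Q, -0.0118 to -0.0050 points and -2.94 to -1.33 for the 5p share and arm ratio of D1709N, and 1.10 to 3.59 points for its main end. Of the 84 named classes, library size alone kept 75, DESeq2 80, its size factors 78, the block 82 and no filter 65; of 62 at a mean of 20 counts 58 were kept. The class from base 35 to 54 with added CU turned in D1709N with library size (-0.12) and ranged from -0.31 (without D1709N sh22bp replicate 2) to 0.69 (without replicate 1) over single libraries left out. The cause was not tested. A library left alone in its group is assumed to vary like the others. Alternatives set beforehand that need microRNA names (list tests, list scaling, construct rows left out, medians over hairpins, dominant hairpins) were not run. Depth limits the 3p starts of pri-mir-30a with E1564A and the 5p shares of the shRNAs.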

Other observations

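The test in this part was chosen after the result was seen. In sh2122bp, 3p reads started at both base 35 and base 36. A candidate explanation is that its ends are a weighted mix of those of sh21bp and sh22bp. A mix matched at base 36 would give 46.6% ± 4.31 of DICER-WT reads at base 35, where 58.5% ± 0.611 (SD, n = 2) were seen, and 9.71% ± 4.03 at base 37, where 1.17% ± 0.171 were seen. With D1709A it would give 30.8% at base 34, where 8.65% ± 0.177 were seen. The sh2122bp ends are thus not such a mix, and the hypothesis is set aside.

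Reads of pri-mir-30a ending at base 45 carried further bases more often with the substitutions in the WT precursor. Those without any were 24.6% ± 0.732 (SD, n = 2) with DICER-WT, 3.22% ± 1.76 with E1564A and 0.732% ± 0.143 with E1564Q (log2 fold change -2.93, SE 0.36, and -5.07, SE 0.40). In MT they were 58.1% ± 2.64, 42.3% ± 6.49 and 51.5% ± 5.08, and neither change passed (adjusted p = 0.641 and 0.923, edgeR). A C after base 45 in WT, and an A in MT, read as template and are not seen as additions. An added A in WT, or an added C in MT, has the sequence of the other precursor's product ending at base 46. Such reads could also come from that precursor. Reads of the 3p arm that reach into the loop were 0.0087% ± 0.0104 (SD, n = 4) with DICER-WT, 0.0497% ± 0.0443 with E1564A and 0.0923% ± 0.0865 with E1564Q.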
